A study of Mus musculus with 14 samples.

How the data were processed

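RNA was measured on 14 Affymetrix Mouse Gene 1-ST arrays of 5 sorted populations: mature mTECs (EpCAM-positive, Ly51-negative, MHC class II high, 4 arrays), immature mTECs (MHC class II low, 4 arrays), cTECs (EpCAM-positive, Ly51-positive, 3 arrays), GFP-positive CD19-positive thymic B cells (2 arrays) and splenic CD19-positive B cells (1 array). Per the labels, cells from typically 3 mice of 6 weeks were pooled, and RNA of about 30000 cells was amplified and 6 micrograms of RNA were labelled. The deposited values are intensity values on a linear scale, from 4.45 to 21463, made by robust multi-array averaging (RMA) per the submitters' processing notes. The software, its version and the arrays normalised together were not given in the sources used here. The log2 of each value was taken before any fit. No array was identical to another. The number of arrays limits the precision, and the p-values describe the spread between pooled samples, most of them TEC samples.

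Of 34760 probe sets, 21640 carried exactly 1 gene symbol, 1321 carried several and 11799 were not listed in the annotation used here. For each of the resulting 19937 genes the probe set with the highest mean was taken, which was a choice among several for 954 genes. No dim gene was left out. Gene names were checked against a gene table of assembly GRCm38, which held 21553 of the probe sets; no positions were used. Symbols without a listed probe set, Tcf7, Cd19, Aicda, Nfkb1 and Stat1 among them, were not analysed here.

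All comparisons came from 1 fit in limma 3.58.1 (R 4.3.3) with a mean for each of the 5 groups over the 14 arrays, 9 residual degrees of freedom and 4.69 prior degrees of freedom. The tests were two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of adjusted p 0.05. The comparisons were mature against immature mTECs, mature mTECs against cTECs, immature mTECs against cTECs, thymic against splenic B cells, and the difference between the first and the last. Overlaps were tested with Fisher's exact test, one-sided, and the count in both comparisons of mature mTECs was set against 20 simulations of unchanged groups. The comparisons, gene lists, named-gene rule and first alternatives were fixed before the data were examined.

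The 29 gene lists held 497 gene names, of which 449 were measured. They covered Aire regulator candidates, sort and reporter genes, MHC class II, costimulation ligands, MHC class I and proteasome, Aire-target and Aire-independent tissue antigens, keratinized, tuft-like and immature mTEC genes, and mature mTEC chemokines. Further lists were the cTEC programme, Notch ligands and thymus factors, NF-kB, interferon-stimulated genes, cell cycle, Aire partner proteins and 4 B-lineage lists (pan-B-cell, mature splenic, activation, plasma cell). The rest were markers of thymocytes, dendritic cells and macrophages, fibroblasts, endothelium and erythroid cells, epithelial identity, immediate-early and ribosomal protein genes. Each was tested with camera in limma at a preset correlation of 0.01, adjusted over the 29 lists of a comparison, and again with an estimated correlation and with fry. Members were counted over all genes and adjusted over the list alone. A list's direction is that of its test; the value given is the median of its members.

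Named genes were Aire, the regulator candidates, Fezf2, G6pc2 and sort genes; per comparison the 10 largest rises and 10 largest falls past the threshold whose arrays did not overlap between the groups; per list up to 4 members; and the first 12 of an overlap. Transcription factors were marked from a list of which 268 were measured. Other named genes are said to be chosen after their values were seen.

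The replicate numbers were checked for pairing through the correlation, across genes, of the deviations from the group mean. Mature and immature mTECs with the same number correlated at 0.465, 0.402, 0.658 and 0.769. Over numbers 1 to 3 alone the values were 0.467, 0.046 and 0.436, so a pairing was not established for number 2. The labels do not say that a shared number marks a shared pool or day. The main fit therefore has no block, and a replicate block was fitted as an alternative. Mature mTECs and cTECs gave -0.087, -0.034 and 0.121. Other alternatives were quantile normalization, median centring, leaving out genes below the 40th percentile, fewer arrays in the fit, an intensity trend with a robust prior, array weights, other uses of probe sets, stricter thresholds, and leaving out each replicate. A block for the number 4 mTEC arrays with the B-cell arrays, leaving out both number 4 arrays, a replicate block on the 8 mTEC arrays and the signal range of each array as a covariate were chosen after the data were seen.

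The fit was tested on simulated data with 50 genes changed at each of 4 sizes. At 2-fold it recovered 40% of them for mature against immature mTECs, 26% for mature mTECs against cTECs, 20% for immature mTECs against cTECs and 2% for the B cells; at 4-fold these were 94%, 94%, 88% and 40%. Between 3 and 11 unchanged genes were called per comparison. The simulated noise was independent between genes and arrays, without outlying arrays or differing signal ranges. These rates therefore do not carry over to the real arrays.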

Results

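The series asked which transcriptional regulators go with expression of Aire, the nuclear protein that lets medullary thymic epithelial cells (mTECs) transcribe tissue-restricted antigens. Gene expression was measured on 14 Affymetrix Mouse Gene 1-ST arrays, each hybridised with amplified RNA from about 30000 sorted cells, with typically 3 mice pooled per sample. Mice were C57BL/6 and 6 weeks old. Mature mTECs with high surface MHC class II made up 4 arrays, immature mTECs with low MHC class II another 4, and cortical thymic epithelial cells (cTECs), sorted as EpCAM-positive and Ly51-positive, another 3. From Adig mice, whose Aire-driven transgene carries green fluorescent protein (GFP), CD19-positive GFP-positive thymic B cells gave 2 arrays and splenic CD19-positive B cells 1 array. The splenic array has no replicate, so tests against it assume that it varies like the other groups. Because samples were pools, the p-values describe the spread between pooled samples, and the number of arrays limits the precision. In the shared fit this spread comes mostly from TEC arrays, for the comparison of the B cells too.

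The array medians were close, from 5.37 to 5.69 on the log2 scale, but the interquartile range of the signal differed. It ran from 2.10 to 2.27 in cTECs, 2.36 to 2.57 in immature mTECs 1 to 3, and 2.55 to 2.76 in mature mTECs 1 to 3. It was 3.03 and 3.20 in mature and immature mTECs 4, and 2.70 to 3.03 in the B cells. The mTEC arrays numbered 4 stood apart from their groups. Mature mTEC 4 correlated with mature mTECs 1 to 3 at r between 0.901 and 0.923 across genes, against 0.974 to 0.982 among those 3. Immature mTEC 4 correlated with immature mTECs 1 to 3 at 0.80 to 0.89 against 0.929 to 0.962. Both number 4 arrays carried Xist, the RNA of the inactive X chromosome, at 9.23 and 9.38, where the other TEC arrays lay between 3.73 and 5.29 and the B-cell arrays between 11.01 and 11.64. The Y-linked genes were highest in the number 4 arrays too. Kdm5d read 6.46 and 6.78 there and 5.02 to 6.14 in the other TEC arrays, Uty 7.86 and 8.15 against 4.13 to 7.25, and Eif2s3y 7.93 and 7.78 against 4.79 to 7.15. Thymic B arrays 1 and 2 differed, with Kdm5d at 3.95 and 5.58, Uty at 3.72 and 6.10, and Eif2s3y at 3.63 and 5.74. The splenic array read 4.55, 4.57 and 5.17 for these genes. Ptprc, the leukocyte marker CD45, was at 7.35 and 7.21 in these 2 arrays and between 5.10 and 5.76 in the other TEC arrays. The median of 51 small nucleolar RNA genes was 7.32 and 7.35 in the number 4 arrays and 7.18 to 7.64 in the B cells, but 4.93 to 6.38 in the other 9 TEC arrays. Xist, Kdm5d, Uty, Eif2s3y, Ptprc and this RNA class were chosen after their values were seen.

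**Figure D1:**
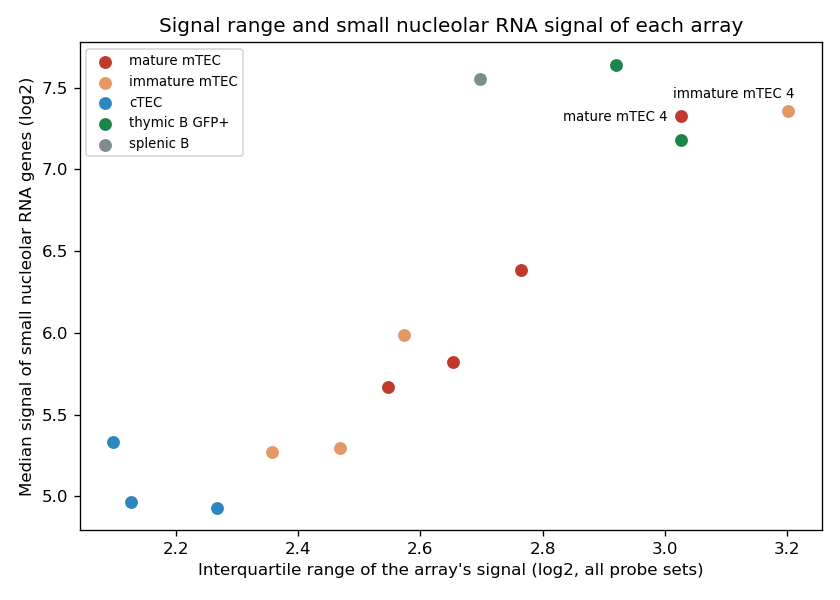
Each point is 1 array, coloured by group; the x axis gives the interquartile range of the log2 signal over all probe sets and the y axis the median log2 signal of 51 small nucleolar RNA genes. The number 4 mTEC arrays, at 7.32 and 7.35, lie with the 3 B-cell arrays and above the other 9 TEC arrays.

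Aire itself was measured by 1 probe set. Its log2 signal was 10.96 ± 0.59 (SD, n = 4) in mature mTECs, 7.44 ± 0.66 (SD, n = 4) in immature mTECs, 7.54 ± 0.25 (SD, n = 3) in cTECs, 9.39 ± 0.26 (SD, n = 2) in GFP-positive thymic B cells and 6.21 in the splenic B-cell array. Mature mTECs exceeded immature mTECs by 3.51 (SE 0.34, adjusted p = 3.46e-05) and cTECs by 3.42 (SE 0.36, adjusted p = 4.62e-05), and immature mTECs and cTECs differed by less than the spread between arrays, with a log2 fold change of -0.10 (SE 0.36, adjusted p = 0.862). The difference between mature and immature mTECs was 3.51 with the replicate block (adjusted p = 1.16e-07) and 3.54 without both number 4 arrays (adjusted p = 5.35e-08). Thymic B cells exceeded splenic B cells by 3.18 (SE 0.58, adjusted p = 0.0209). This last call was lost when thymic B array 1 was left out (adjusted p = 0.17), when thymic B array 2 was left out (adjusted p = 0.0746) and after quantile normalization (log2 fold change 2.63, adjusted p = 0.207).

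The regulators that the study is known to have followed up, chosen partly on these samples and so not independent evidence, were examined next. Irf4, an interferon regulatory factor of activated lymphocytes, was 2.25 higher in mature than in immature mTECs (SE 0.23, adjusted p = 4.47e-05). Irf8, a related factor, was 1.84 higher (SE 0.43, adjusted p = 0.0161), and Tbx21, which encodes T-bet, 1.79 higher (SE 0.24, adjusted p = 0.000403). Ctcfl, a germline paralogue of the insulator protein CTCF, had a log2 fold change of 0.75 (SE 0.22) that did not pass (adjusted p = 0.0547). It passed with the replicate block, which pairs mature with immature samples of the same number (adjusted p = 0.00804), without mature mTEC 4 (adjusted p = 0.0232) and without immature mTEC 3 (adjusted p = 0.0443). It also passed after quantile normalization, after median centring, with array weights and with the signal range covariate. So it did without both number 4 arrays, with their block and with the block on the 8 mTEC arrays. It did not pass with fewer groups in the fit, without dim genes, with the intensity trend or with probe set means. Nor did it pass without mature mTEC 1, 2 or 3 or immature mTEC 1, 2 or 4. The adjusted p of Ctcfl lay between 0.00062 and 0.164 over all alternatives. Against cTECs, mature mTECs were higher for Irf4 by 2.79 (adjusted p = 1.22e-05), Irf8 by 1.95 (adjusted p = 0.00689) and Tbx21 by 1.16 (adjusted p = 0.00524), while Ctcfl did not pass (0.11, adjusted p = 0.719). In the B-cell comparison none of these passed: Irf4 stood at 8.90 ± 0.61 (SD, n = 2) in thymic and 8.37 in splenic B cells, Irf8 at 10.49 ± 0.05 (SD, n = 2) and 10.35, Tbx21 at 6.98 ± 0.40 (SD, n = 2) and 6.28, and Ctcfl at 4.72 ± 0.08 (SD, n = 2) and 4.87 (adjusted p = 1 for each). The difference between the mTEC and B-cell contrasts did not pass for Irf4 (1.72, SE 0.45, adjusted p = 0.108), Irf8 (1.71, SE 0.85, adjusted p = 0.608), Tbx21 (1.08, SE 0.48, adjusted p = 0.497) or Ctcfl (0.89, SE 0.44, adjusted p = 0.594). Of the 5 measured candidates, Aire included, 4 were higher in mature than in immature mTECs (5 adjusted over the list alone), and this list alone kept its call in that comparison with an estimated correlation (camera adjusted p = 8.67e-09, and 0.00458 estimated). Tcf7 was not analysed here.

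**Figure D2:**
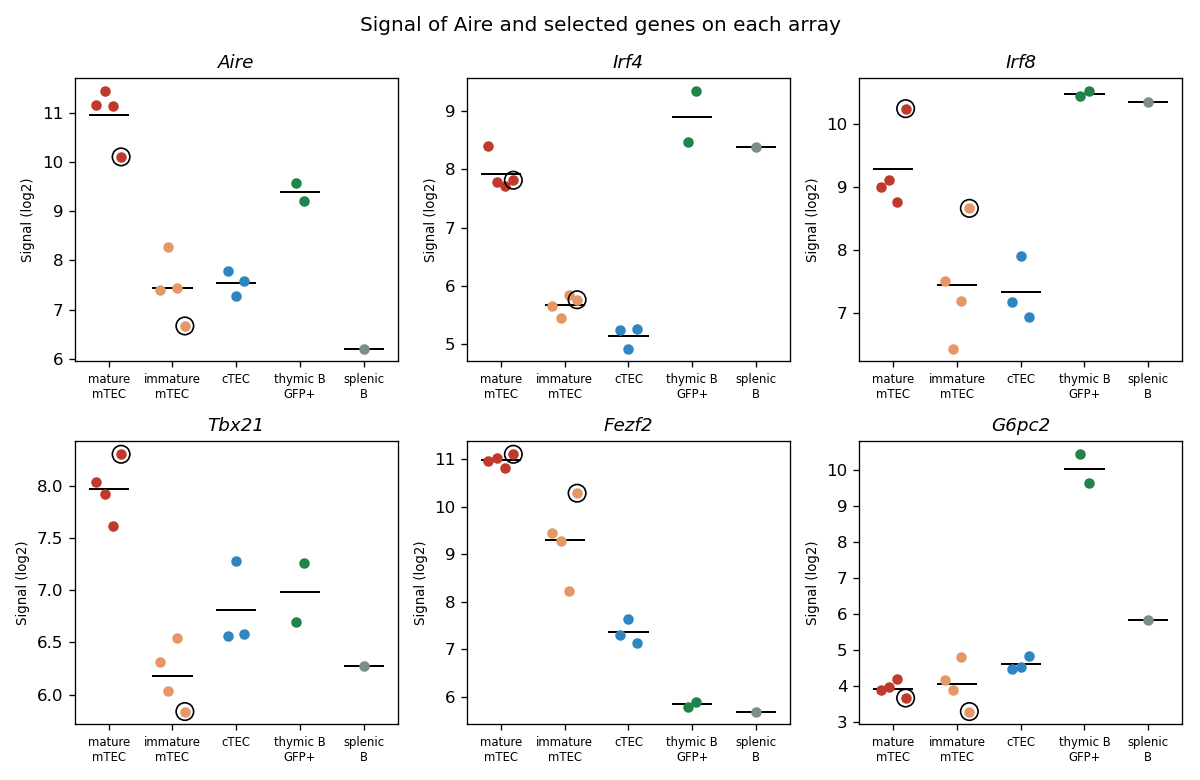
Log2 signal of Aire, Irf4, Irf8, Tbx21, Fezf2 and G6pc2 on each of the 14 arrays, by group; points are arrays, open circles mark the mTEC arrays numbered 4, and horizontal bars are group means. Aire reached 10.96 in mature mTECs and 9.39 in GFP-positive thymic B cells, against 6.21 to 7.54 in the other 3 group means.

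Mature against immature mTECs separates the Aire-expressing medullary cells from their less mature counterparts. Mature mTECs had 994 genes higher and 564 lower of 19937 tested, with 784 and 300 of them changed at least 2-fold. The largest rises were in H2-Eb2, an MHC class II beta chain (log2 fold change 4.09, SE 0.43), Ccl25, a chemokine that draws thymocyte progenitors (4.03, SE 0.54), and Hdc, the enzyme that makes histamine (4.00, SE 0.23). Next came Nos2, inducible nitric oxide synthase (3.94, SE 0.25), and Ly6g, a neutrophil surface antigen (3.91, SE 0.43), followed by Serpinb12, Gpr50, the prostaglandin synthase Ptgs2, the milk protein gene Csn2 and Skint4, between 3.54 and 3.79. The largest falls were in Lifr, the leukaemia inhibitory factor receptor (-3.33, SE 0.41), Wfikkn2 (-2.93), Boc (-2.83) and Trpm5, the cation channel of taste and tuft cells (-2.75). These were followed by Fgfr2, the receptor for epithelial fibroblast growth factors (-2.68), and by Scn7a, Tagln, the taste receptor Tas2r118, Cd177 and Dclk1, between -2.67 and -2.48. All 20 had adjusted p of 0.0108 or below.

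Over the 29 lists, 18 passed camera for mature against immature mTECs, 1 with an estimated correlation and 12 with fry. The gate that parts mature from immature mTECs selects on MHC class II itself. Of 11 measured MHC class II genes, 9 were higher (9 adjusted over the list alone), led by the peptide-loading modulators H2-Oa (2.81) and H2-Ob (2.31), while the gated H2-Aa was 1.5 higher (adjusted p = 0.0094). The list passed camera at adjusted p = 3.76e-11, with adjusted p = 0.0875 at an estimated correlation. Of 15 costimulation and checkpoint ligands, 9 were higher (10 over the list alone), led by Cd80 (3.50) and Icosl (2.68), with adjusted p = 6.43e-09 and adjusted p = 0.0695 with an estimated correlation. For MHC class I and the proteasome, 2 of 11 were higher (5 over the list alone), the proteasome activators Psme2 (1.28) and Psme1 (0.83), with adjusted p = 0.000264 and adjusted p = 0.202 with an estimated correlation. Of 21 NF-kB pathway genes, 10 were higher (13 higher and 2 lower over the list alone), led by the decoy receptor gene Tnfrsf11b (2.07) and the receptor Cd40 (1.84), with adjusted p = 1.05e-06 and adjusted p = 0.149 with an estimated correlation.

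Tissue-restricted antigens used as readouts of Aire were higher for 6 of 16 members (8 over the list alone), led by the testis lipid-binding protein Fabp9 (2.93) and the apolipoprotein Apoa4 (2.66), with adjusted p = 5.83e-07 and adjusted p = 0.0695 with an estimated correlation. The list held to depend little on Aire had 5 of 11 higher (5 over the list alone), led by Csn2 (3.56) and Apob (2.18), adjusted p = 3.46e-06 and adjusted p = 0.0569 with an estimated correlation. Of 15 chemokines and cytokines of mature mTECs, 5 were higher (8 over the list alone), led by Ccl5 (2.65) and Ccl22 (2.62), with adjusted p = 6.93e-08 and adjusted p = 0.0875 with an estimated correlation. Over this list array 4 exceeded arrays 1 to 3 by a median of 0.88 in mature and 1.3 in immature mTECs. Of 24 B-cell activation genes, 11 were higher (12 higher and 2 lower over the list alone), with Cd80 and Irf4 leading, adjusted p = 5.83e-07 and adjusted p = 0.0875 with an estimated correlation. Fezf2, a second transcription factor of antigen expression in mTECs, was 1.67 higher (SE 0.33, adjusted p = 0.00553).

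Immature mTECs held the tuft-like programme. Of 18 tuft genes, 10 were lower in mature mTECs (15 over the list alone) and none higher, with a median log2 fold change of -2.05, led by the taste transducin Gnat3 (-3.01) and Trpm5 (-2.75), camera adjusted p = 7.68e-14 and adjusted p = 0.0875 with an estimated correlation. Over the tuft genes array 4 exceeded arrays 1 to 3 by a median of 1.34 in mature and 0.58 in immature mTECs. The immature and CCL21 list had 5 of 16 lower and 1 higher (7 and 1 over the list alone), with Lifr and Igfbp5 (-2.36) lower and Tnfrsf11b higher, adjusted p = 0.0224 and adjusted p = 0.551 with an estimated correlation. Interferon-stimulated genes were lower for 6 of 20 and higher for 1 (7 and 1 over the list alone), with Ddx58 (-1.76) and Oas2 (-1.75) lower and Oasl1 (0.81) higher, and the list did not pass (adjusted p = 0.0747). Over this list array 4 exceeded arrays 1 to 3 by a median of 0.52 in mature and 1.30 in immature mTECs, and without both number 4 arrays 7 were lower and 4 higher. None of 17 keratinized mTEC genes passed (0 over the list alone; list adjusted p = 0.589), the largest values being 1.52 for Sprr1b and 0.92 for Krt77. The number 4 arrays exceeded numbers 1 to 3 by a median of 1.90 in mature and 2.54 in immature mTECs over these genes. Genes of the cTEC programme went both ways, with 7 of 19 higher, led by Ccl25 and Tbata (2.52), and 3 lower, with Fgfr2 and Pltp (-1.57) at their head (7 and 8 over the list alone; list adjusted p = 0.327). Enpep, which encodes the Ly51 antigen excluded by the mTEC gate, was 1.13 higher in mature mTECs (SE 0.29, adjusted p = 0.0301).

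Markers of other cells were mixed in this comparison. Of 20 dendritic and macrophage markers, 2 were higher, Lyz2 (3.02) and Mrc1 (2.15) (2 over the list alone), with adjusted p = 0.0463 and adjusted p = 0.581 with an estimated correlation. Over this list array 4 exceeded arrays 1 to 3 by a median of 1.21 in mature and 0.96 in immature mTECs. Lyz2 stood at 10.31 ± 0.66 (SD, n = 4) in mature and 7.28 ± 1.64 (SD, n = 4) in immature mTECs. Thymocyte markers had 1 of 19 higher, Cd3g (1.35). Fibroblast markers had 1 of 14 higher, Pdgfrb (1.66), and 3 lower, with Col6a1 (-2.13) and Col6a2 (-2.05) at their head. Neither list passed (adjusted p = 0.65 and 0.381; 1 higher, and 1 higher with 3 lower, over each list alone). Endothelial markers had no member past the threshold among 13 (0 over the list alone) but values below 0 in 12 and a median of -0.34, adjusted p = 0.0408 and adjusted p = 0.396 with an estimated correlation. That list's call was lost with fry, after quantile normalization, with array weights, with the signal range covariate, without both number 4 arrays, and without mature mTEC 1, mature mTEC 4, immature mTEC 3 or immature mTEC 4. Erythroid markers were higher for 3 of 6 (3 over the list alone), led by Epb42 (1.84) and the transferrin receptor gene Tfrc (1.46), adjusted p = 0.00955 and adjusted p = 0.274 with an estimated correlation. None of 17 immediate-early and heat-shock genes passed (0 over the list alone), with -1.34 for Fos and -1.08 for Jun (list adjusted p = 0.381). Of 7 sort and reporter genes 4 were higher (4 over the list alone), H2-Aa and H2-Eb1 among them, adjusted p = 0.00335 and adjusted p = 0.0875 with an estimated correlation. The cell-cycle, pan-B-cell and plasma-cell lists passed camera upward, with adjusted p = 0.00209, 0.0249 and 0.0408, and adjusted p = 0.353 for each with an estimated correlation. Of their members 2 of 31, 3 of 21 and 2 of 14 were higher past the threshold. The counts moved with single arrays and with the design. The lower genes numbered 305 without mature mTEC 1, 290 without mature mTEC 2 and 369 without immature mTEC 1, and without mature mTEC 4 there were 948 higher and 582 lower. Without immature mTEC 4 there were 2397 genes higher and 2095 lower, without both number 4 arrays 2327 and 1786, and with the replicate block, in which the shared number pairs mature with immature samples, 1925 and 1410.

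Mature mTECs against cTECs sets the Aire-high medulla against the cortical lineage. Mature mTECs had 3450 genes higher and 4569 lower, of which 2611 and 1852 changed at least 2-fold. The largest rises were in Skint9 (5.45), Ptgs2 (5.43), the phosphoinositide kinase Pip5k1b (5.21), and Lypd8, a colonic antibacterial protein (4.93). Then came Aoc1, diamine oxidase (4.78), and the Paneth-cell lysozyme Lyz1 (4.72), followed by 2210407C18Rik, Skint4, Serpinb12 and Saa3, between 4.62 and 4.71. The largest falls were in Prss16, the cortical thymus-specific serine protease (-3.59, SE 0.66), Lifr (-2.95), and the endothelial cadherin Cdh5 (-2.72). They included the fatty acid receptor Cd36 (-2.55), the endothelial growth factor receptor Kdr (-2.54), Gas1 (-2.50), the chemokine Cxcl12 (-2.46) and Ccn1 (-2.46), and 2 further genes in this set were a predicted gene and an antisense transcript. All 20 had adjusted p of 0.0311 or below.

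The cTEC programme had 9 of 19 genes lower in mature mTECs (11 over the list alone) and 1 higher, Foxn1 (1.63), the master factor of thymic epithelium, with adjusted p = 0.00804 and adjusted p = 0.492 with an estimated correlation. All lists in this comparison lost their call with an estimated correlation, at adjusted p = 0.123 or more. With fry 20 of the 29 lists passed. MHC class II genes were higher for 10 of 11 (10 over the list alone), led by Ifi30 (3.51) and H2-Oa (3.10), adjusted p = 1.15e-07 and adjusted p = 0.244 with an estimated correlation. Costimulation ligands were higher for 9 of 15 (9 over the list alone), with Cd80 at 4.54. MHC class I genes were higher for 8 of 11 (8 over the list alone). NF-kB genes were higher for 13 of 21 with 1 lower (14 and 2 over the list alone), led by the RANK gene Tnfrsf11a (2.75) with Ltbr (-0.80) lower. Mature mTEC chemokines were higher for 8 of 15 with 1 lower (8 and 1 over the list alone), led by Ccl19 (3.92) and Cxcl9 (3.34) with Il6 (-1.48) lower. Aire-target antigens were higher for 6 of 16 with 1 lower (6 and 1 over the list alone), and the less Aire-dependent antigens for 5 of 11 (5 over the list alone). Aire partner proteins were higher for 11 of 20 (12 over the list alone), led by the deacetylase gene Sirt1 (3.84) and Ccnt1 (1.94). These 7 lists passed camera with adjusted p of 0.00804 or below, and each stood at adjusted p = 0.244 or 0.245 with an estimated correlation. Fezf2 was 3.62 higher (SE 0.35, adjusted p = 2.36e-05).

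Ribosomal protein genes were higher for 14 of 22 with 1 lower (14 and 1 over the list alone), led by Rps6 (2.39) and Rpl10a (2.02), adjusted p = 5.18e-05 and adjusted p = 0.244 with an estimated correlation. Epithelial identity genes were higher for 10 of 20 with 1 lower (10 and 1 over the list alone), led by Cldn4 (2.82). Keratinized genes were higher for 7 of 17 (7 over the list alone), led by Sprr1a (4.01). Over the keratinized genes mature mTEC 4 exceeded mature mTECs 1 to 3 by a median of 1.90. The 2 lists had adjusted p = 0.000184 and 0.000867, and adjusted p = 0.328 and 0.492 with an estimated correlation. Endothelial markers were lower in mature mTECs for 10 of 13 (11 over the list alone), with Cdh5 at 7.64 ± 0.53 (SD, n = 3) in cTECs and 4.91 ± 0.46 (SD, n = 4) in mature mTECs. Kdr stood at 7.11 ± 1.05 (SD, n = 3) and 4.58 ± 0.22 (SD, n = 4), and the list had camera adjusted p = 5.18e-05 and adjusted p = 0.244 with an estimated correlation. Fibroblast markers were lower for 7 of 14 and higher for 1 (8 and 1 over the list alone), and thymocyte markers were lower for 8 of 19 and higher for 3 (8 and 3 over the list alone). Neither list passed camera (adjusted p = 0.101 and 0.135). The regulator candidate, B-cell activation and sort gene lists also passed camera upward (adjusted p = 0.000638, 0.000867 and 0.0411). Of their members 4 of 5, 10 of 24 (with 1 lower) and 4 of 7 were higher past the threshold.

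The cTEC arrays had the narrowest signal range, and the 7 arrays of this comparison are ordered by range exactly as by group, so that range and cell type were not separated. By mean TEC signal, the dimmest 10% of genes had a median log2 fold change of -0.49 and the brightest 10% of 1.05. These became -0.13 and 0.32 after quantile normalization, which gave 3067 genes higher and 3857 lower. All genes together had a median of -0.22. With each array's signal range as a covariate, chosen after the data were seen, 1422 genes were higher and 1744 lower, of which 1160 and 657 were also called without it, and the keratinized list turned to a median of -0.96 (adjusted p = 0.205). Median centring of each array gave 4034 higher and 2629 lower, so that 60.5% of calls were higher instead of 43.0%. The count of lower genes was 2931 without mature mTEC 1, 2919 without mature mTEC 4, 2499 without cTEC 1 and 2443 without cTEC 3, and without both number 4 arrays 4277 were higher and 5930 lower.

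Immature mTECs against cTECs compares the 2 Aire-low epithelia. Immature mTECs had 921 genes higher and 593 lower. The largest rises belonged to tuft-cell genes, Gnat3 (4.31, SE 0.85), Trpm5 (3.99, SE 0.41) and the kinase Dclk1 (3.38, SE 0.49), and to Clca3b (3.96), Adgrg6 (3.67), Snord57 (3.47), Mctp1 (3.47), Cd24a (3.37), Sprr1a (3.27) and Clca3a2 (3.21). The largest falls belonged to Ccl25 (-3.96), Prss16 (-3.88), the endocytic receptor Ly75 (-2.54), Cdh5 (-2.14), Tbata (-2.11), Pecam1 (-2.06), Kdr (-1.97), Enpep (-1.92), Cxcl12 (-1.84) and the water channel Aqp1 (-1.81). All 20 had adjusted p of 0.0279 or below.

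Of 18 tuft genes, 12 were higher in immature mTECs than in cTECs (15 over the list alone), with a median of 2.08, camera adjusted p = 8.59e-14 and adjusted p = 0.396 with an estimated correlation. The cTEC programme was lower for 10 of 19 (11 over the list alone) and none of it higher, adjusted p = 1.22e-05 and adjusted p = 0.57 with an estimated correlation. Epithelial identity genes were higher for 8 of 20 (11 over the list alone), led by Krt14 (2.03) and Elf3 (1.79), adjusted p = 1.48e-07 and adjusted p = 0.466 with an estimated correlation. Immature and CCL21 genes were higher for 3 of 16 (6 over the list alone), with Krt14 and Krt17 (1.68) leading, and interferon-stimulated genes for 2 of 20 (5 over the list alone), Irf7 (1.52) and Stat2 (1.06), with adjusted p = 0.00376 and 0.000158, and adjusted p = 0.57 for both with an estimated correlation. Fezf2 was 1.95 higher (SE 0.35, adjusted p = 0.00934), and Notch ligand and thymus factor genes included Spib (2.81) and Eya1 (2.19) higher and Dll4 (-1.32) lower, with 4 of 15 higher and 1 lower (4 and 2 over the list alone; list adjusted p = 0.111). Endothelial markers were lower in immature mTECs for 8 of 13 (10 over the list alone), adjusted p = 1.5e-05 and adjusted p = 0.396 with an estimated correlation. The keratinized, ribosomal protein, NF-kB, MHC class II and MHC class I lists also passed camera upward (adjusted p = 2.52e-05, 6.57e-06, 0.00129, 0.00642 and 0.02). Of their members 3 of 17, 5 of 22, 1 of 21, 0 of 11 and 1 of 11 were higher past the threshold. With an estimated correlation these lists had adjusted p of 0.436 or more. The keratinized and MHC class II lists reversed with the signal range covariate and the MHC class I list after quantile normalization. Over the keratinized genes immature mTEC 4 exceeded immature mTECs 1 to 3 by a median of 2.54. With the signal range as a covariate 258 genes were higher and 333 lower, the median of the interferon-stimulated list turned to -0.13 (adjusted p = 0.537) and the immature and CCL21 list stood at 0.01 with its test turned downward, not past the threshold. Median centring made 75.1% of calls higher instead of 60.8%. The counts of higher and lower genes were 312 and 104 without immature mTEC 1, 2193 and 2098 without immature mTEC 3, 611 and 323 without immature mTEC 4, 220 and 102 without cTEC 1, 154 and 53 without cTEC 3, and 1341 and 871 without both number 4 arrays.

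GFP-positive thymic B cells were set against splenic B cells to find what accompanies Aire outside the epithelium. No GFP-negative thymic B cells were measured, so Aire cannot be told apart from organ, activation or cell cycling in this comparison. Thymic B cells had 137 genes higher and 22 lower, each changed at least 2-fold. The largest rises were in Ccl22, a chemokine of mature dendritic cells and activated B cells (6.00, SE 0.90), the carboxypeptidase Cpd (4.65, SE 0.67), Fscn1, the actin-bundling protein of mature dendritic cells (4.65, SE 0.42), and Gatm, the first enzyme of creatine synthesis (4.34, SE 0.52). Next were G6pc2 (4.22, SE 0.50), whose IGRP sequence the Adig transgene carries, the inhibitory receptor Lilrb4a (4.22), Nostrin (4.02), Havcr1, which encodes TIM-1 (4.00), the cytokine receptor Flt3 (3.89) and Cd96 (3.83). The largest falls were in Cyp39a1 (-2.81), the B-lineage genes Ralgps2 (-2.79) and Vpreb3 (-2.77), and Cacna1i (-2.50). Then came Brwd1 (-2.48), the Notch target Dtx1 (-2.48) and Zfp318, a regulator of IgD splicing (-2.47), followed by Dnah8, Hhex and Lmo2, between -2.20 and -1.96. All 20 had adjusted p of 0.0455 or below.

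Cell-cycle genes formed the group with the most calls. Of 31, 12 were higher in thymic B cells (29 over the list alone), with a median of 1.84, led by Ccnb2 (3.22) and Top2a (3.09), camera adjusted p = 1.17e-56 and adjusted p = 0.00196 with an estimated correlation. B-cell activation genes were higher for 3 of 24 (9 over the list alone), led by the death receptor Fas (3.19) and the interleukin-9 receptor Il9r (2.93), with adjusted p = 4.31e-10 and adjusted p = 0.0406 with an estimated correlation. Costimulation ligands were higher for 2 of 15 (8 higher and 1 lower over the list alone), Tnfsf9 (3.30) and Cd70 (2.31), and plasma-cell genes for 1 of 14 (2 over the list alone), the joining-chain gene Jchain (2.65), with adjusted p = 3.52e-09 and 2.49e-07, and adjusted p = 0.0406 for both with an estimated correlation. Mature splenic B-cell genes were lower for 1 of 18 (6 over the list alone), Dtx1, with a median of -1.09, adjusted p = 3.52e-09 and adjusted p = 0.0406 with an estimated correlation. Pan-B-cell genes were lower for 2 of 21 (2 over the list alone), Ralgps2 and Vpreb3, adjusted p = 1.86e-05 and adjusted p = 0.0881 with an estimated correlation.

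Interferon-stimulated genes passed for none of 20 over all genes and for 4 over the list alone. Their values lay above 0 for 19 of 20, with 3.15 for Usp18 and 2.45 for Ifih1, and the list had camera adjusted p = 3.71e-12 but adjusted p = 0.163 with an estimated correlation. Neither the Aire-target nor the less Aire-dependent antigens had a gene past the threshold among 16 and 11 (0 over each list alone), with medians of -0.07 and -0.35 and adjusted p = 0.276 and 0.599. Thymocyte markers were higher in thymic B cells for 4 of 19 (11 over the list alone), led by Themis (3.05) and Cd8a (2.36), camera adjusted p = 2.33e-15 and adjusted p = 0.0167 with an estimated correlation. Of 20 dendritic and macrophage markers 1 was higher, Flt3 (2 over the list alone), adjusted p = 4.4e-05 and adjusted p = 0.297 with an estimated correlation. Thymic B array 1 held more macrophage transcripts than array 2, with Lyz2 at 11.46 and 8.36 and C1qb at 10.16 and 7.09, against 7.53 and 6.79 in splenic B cells, and Fn1, a member of the fibroblast list, stood at 10.13 and 5.04 against 5.37; C1qb and Fn1 were chosen after their values were seen. Of 20 epithelial identity genes none passed (0 over the list alone; adjusted p = 0.831). The MHC class I, regulator candidate, ribosomal protein, mature mTEC chemokine and immediate-early lists passed camera upward (adjusted p = 0.00252, 0.0111, 0.0142, 0.0368 and 0.0491). Of their members 0 of 11, 1 of 5, 0 of 22, 1 of 15 and 0 of 17 were higher past the threshold. The erythroid list passed downward (adjusted p = 0.00837), with 1 of 6 members lower. With an estimated correlation all of these lists had adjusted p of 0.074 or more. The test of immediate-early genes turned downward, not past the threshold, with the signal range covariate. The counts were 38 higher and 2 lower without thymic B 1, 69 and 8 without thymic B 2, 707 and 205 on the 3 B-cell arrays alone, and 485 and 117 without both number 4 TEC arrays, which enter the shared estimate of spread.

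**Figure D3:**
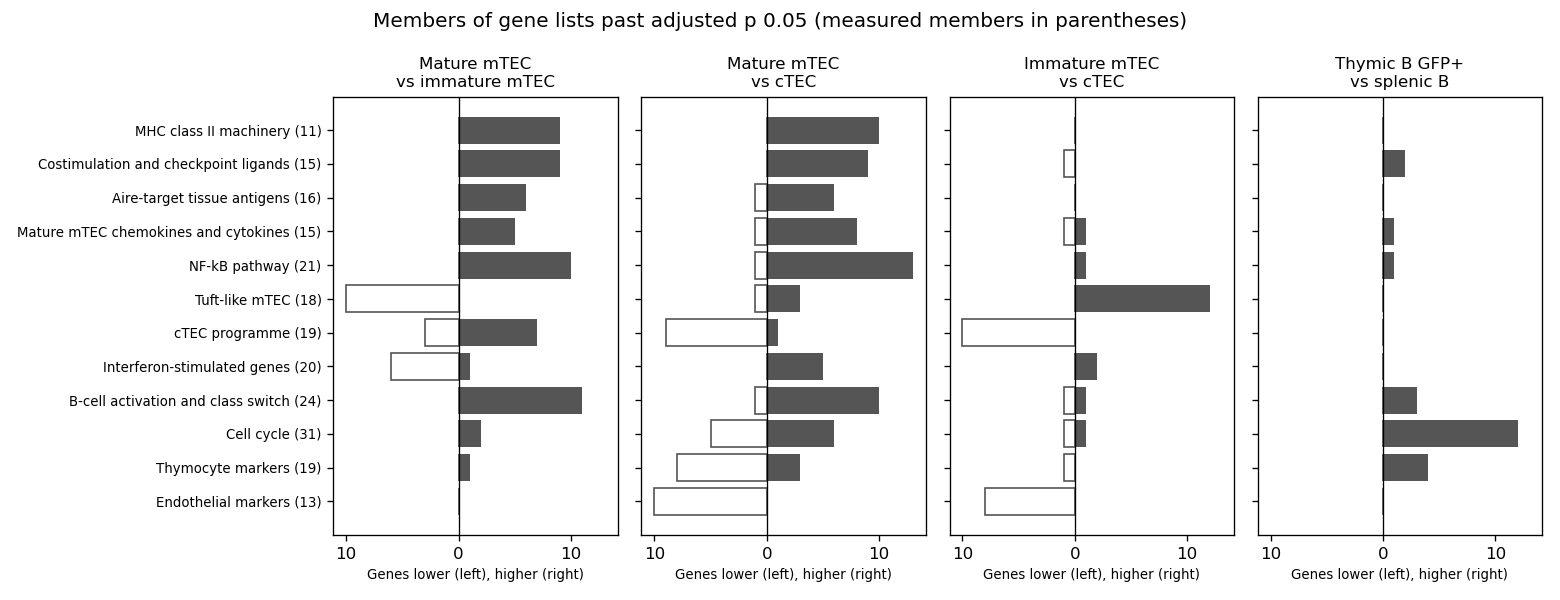
Number of measured members of 12 gene lists that were higher (right, filled) or lower (left, open) at adjusted p below 0.05 over all genes, in each of the 4 comparisons; the x axis counts genes. Tuft genes were lower for 10 of 18 in mature against immature mTECs and higher for 12 of 18 in immature mTECs against cTECs, and cell-cycle genes were higher for 12 of 31 in thymic against splenic B cells.

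The 2 Aire-linked contrasts were then overlaid to find genes higher in both lineages. The B-cell contrast also parts thymus from spleen, so a shared gene need not go with Aire. Genes are not independent replicates, and all contrasts share 1 estimate of spread. The Fisher p-values of the overlaps therefore do not measure the spread between samples. Of the 994 genes higher in mature than in immature mTECs and the 137 higher in thymic than in splenic B cells, 27 were shared, against 6.83 for independent lists (Fisher's exact test, one-sided, p = 7.33e-10), and 21 of them changed at least 2-fold in both. Ranked by the smaller of their 2 log2 fold changes, given here for mTECs and then B cells, the first was Aire (3.51 and 3.18). Then came Gatm (2.84 and 4.34), Ccl22 (2.62 and 6.00) and the G-protein subunit Gnb4 (2.53 and 3.23). The next were Fscn1 (2.45 and 4.65), the interferon-induced GTPase Gbp8 (2.29 and 2.43), the endolysosomal transporter Slc15a3 (2.25 and 2.47), and Tm4sf5 (2.19 and 2.83). The last were Nostrin (2.09 and 4.02), Fas (1.80 and 3.19), Tnfsf9 (1.62 and 3.30) and Tnfrsf10b (1.51 and 2.27). Aire, which drives the reporter used in the B-cell sort, was the only 1 of 268 listed transcription factors among the 27. Only 40% of simulated 4-fold changes were recovered in the B cells, so other shared factors are not excluded. The cell-cycle genes Top2a and Tpx2 were also among the 27. Fewer genes were shared downward, 3 against 0.622 for independent lists (one-sided Fisher's exact p = 0.0232), Lmo2, Nrgn and Cyp2d22. Opposite directions shared 2 (higher in mTECs) and 3 (lower in mTECs) genes, against 1.10 and 3.88. Across genes, which are not independent replicates, the 2 contrasts correlated at Pearson's r = 0.182 and Spearman's rho = 0.162.

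Requiring mature mTECs to exceed cTECs as well left 858 genes, of which 24 were also higher in thymic B cells, against 5.90 for independence (one-sided Fisher's exact p = 4.22e-09); the first 12 by the smallest of their 3 changes included Aire, Gatm, Ccl22, Fscn1, Nostrin and Fas. The comparisons with immature mTECs and with cTECs share the mature mTEC arrays. In 20 simulations of unchanged groups no gene was called in both. With no gene changed hardly any is called, so this cannot show how far the shared arrays raise the count. Independent lists of the sizes found with all arrays would share 172. With 2 of the mature arrays used in each comparison between 308 and 483 genes were shared. No count for independent lists was made for these smaller fits, so 172 is not their reference. By the test of the difference itself, the signed log2 fold change was higher in the mTEC than in the B-cell contrast for 94 genes and lower for 97, with G6pc2 (-4.35, SE 0.58, adjusted p = 0.00415), Nostrin (-1.93, SE 0.40, adjusted p = 0.0406) and Fscn1 (-2.20, SE 0.48, adjusted p = 0.0485) among the named genes. The Adig transgene carries the IGRP sequence of G6pc2, so the difference of this gene cannot be told apart from the transgene. These 191 genes became 35 without thymic B 1, 43 without thymic B 2, 103 without mature mTEC 1, 75 without mature mTEC 2, 118 without mature mTEC 3, 102 without immature mTEC 1, 517 without immature mTEC 4 and 123 without cTEC 3. With 1 array left out, the splenic array excepted, G6pc2 passed each time, with adjusted p of 0.0388 or below. Nostrin passed only without mature mTEC 4, immature mTEC 4, cTEC 1 or cTEC 2 (0.0195 to 0.21 over the 13 arrays), and Fscn1 only without mature mTEC 4, immature mTEC 3 or immature mTEC 4 (0.0257 to 0.183). The 27 shared genes became 8 without thymic B 1, 11 without thymic B 2, 15 without mature mTEC 1, 16 without mature mTEC 2, 14 without immature mTEC 1, 15 without immature mTEC 2, 90 without immature mTEC 4 and 143 without both number 4 arrays. The 24 became 7 without thymic B 1, 9 without thymic B 2, 14 without mature mTEC 1, 15 without mature mTEC 2, 13 without immature mTEC 1, 14 without immature mTEC 2, 15 without cTEC 2 and 78 without immature mTEC 4.

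**Figure D4:**
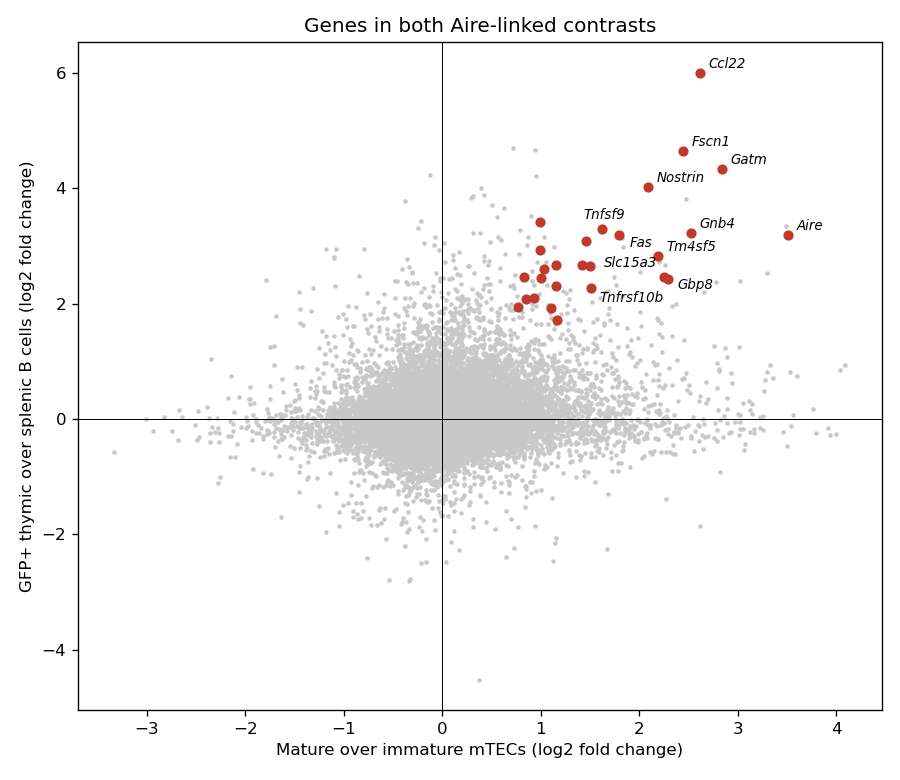
Each grey point is a gene, with its log2 fold change of mature over immature mTECs on the x axis and of GFP-positive thymic over splenic B cells on the y axis; the 27 genes higher in both at adjusted p below 0.05 are filled and the 12 ranked first are named. Aire lies at 3.51 and 3.18, and Ccl22 at 2.62 and 6.00.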

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

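The tests in this part were chosen after the results were seen. In groups of 4 arrays, the gap between the highest or lowest array and its nearest neighbour, as a share of the group's range, was set against Dixon's 95% critical value for 324 pairs of a gene named in the text and an mTEC group. It was passed by 34 pairs, where chance gives about 1 in 20; in 33 of them the array was number 4, and in 32 of these it was the highest. Among the 34, the 7 pairs of Xist, Kdm5d, Uty, C1qa, C1qb and C1qc come from genes chosen after their values were seen.

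In mature mTECs, array 4 was the highest for C1qa (share 0.847), C1qb (0.876), C1qc (0.885), Ccl5 (0.889), Cd24a (0.915), Cd40 (0.839), Cxcl9 (0.82907), Enpep (0.92), Fabp9 (0.902), Lypd8 (0.843), Pltp (0.832), Rps6 (0.883), Saa3 (0.834), Sprr1a (0.879), Sprr1b (0.942), Tbata (0.914), Themis (0.915), Usp18 (0.872) and Xist (0.841). In immature mTECs, array 4 was the highest for Cd24a (0.924), Cd36 (0.882), Cd40 (0.831), Cdh5 (0.834), Gnb4 (0.899), Il6 (0.884), Kdm5d (0.912), Krt77 (0.854), Lypd8 (0.844), Skint9 (0.834), Tnfrsf10b (0.929), Uty (0.865) and Xist (0.969), and the lowest for Hhex (0.89). Irf4 was apart in mature mTEC 1 (0.857), which read 8.40 where the other 3 mature arrays lay between 7.71 and 7.81.

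Both number 4 arrays differed from numbers 1 to 3 in one direction by at least 2-fold in 1948 of 19937 genes, 1679 of them higher, and their differences correlated across genes at r = 0.769. Their wider signal range is argued against as the whole cause, since a wider range keeps the order of the genes, yet their highest rank correlations (Spearman) with their groups were 0.928 and 0.892, below the lowest of 0.972 and 0.931 among numbers 1 to 3. RNA from leukocytes is argued against as the whole cause, since keratinized genes were higher by medians of 1.90 and 2.54, more than the 1.21 of dendritic and macrophage markers in mature mTEC 4. A share of macrophage RNA stays open, with C1qb at 9.98 in mature mTEC 4 and 6.15 to 6.63 in mature mTECs 1 to 3, although the EpCAM gate would remove macrophages. An RNA preparation or labelling shared with the B-cell arrays is a candidate explanation that was not tested. It was prompted by the small nucleolar RNA genes, chosen after their values were seen. The lower of the number 4 arrays' medians of these genes was 7.32, beside 7.18 for the lowest B-cell array and 6.38 for the highest other TEC array. Xist and the Y-linked Kdm5d, at 6.46 and 6.78, were both higher in the number 4 arrays. The labels give no sex for the pooled mice, and no biological explanation was tested.

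By the test of the difference itself, the mTEC contrast and the B-cell contrast differed by -4.35 for G6pc2, -2.20 for Fscn1 and -1.93 for Nostrin (limma, adjusted p = 0.00415, 0.0485 and 0.0406), each larger in the B cells. The B cells were sorted on the Adig transgene, which carries the IGRP sequence of G6pc2. The G6pc2 value thus cannot be told apart from the transgene, and it does not show a difference between lineages. The calls of Nostrin and Fscn1 were lost without either thymic B array and without several TEC arrays.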

How the results depend on the processing

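The alternatives with a block for the number 4 arrays, without both number 4 arrays, with a block on the 8 mTEC arrays and with the signal range covariate were chosen after the data were seen, and the others before. All of those fixed before the data were examined were run. For the named genes, 5625 values kept direction and side of the threshold, 509 no longer passed, 101 newly passed and 2 reversed; for the lists these were 2062, 173, 45 and 11. Simulated 2-fold changes were mostly missed in the B cells (2% recovered), so a gene not called there is not shown to be unchanged. Unless a cause is given, the cause was not tested.

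Array weights gave 3444 higher and 4055 lower for mature against immature mTECs and 1385 and 1066 for immature mTECs against cTECs. They gave 775 and 255 for the B cells, 283 shared by the 2 Aire contrasts, 236 in all 3 comparisons and 2101 that differed. Only the arrays compared gave 614 and 258, 99 and 9, 707 and 205, and 68 and 68 shared. The replicate block gave 1925 and 1410 for mature against immature mTECs and 1648 and 1054 for immature mTECs against cTECs, and on the 8 mTEC arrays 2004 and 1500. The block for the number 4 arrays gave 1979 and 1518, 1812 and 1343, 440 and 103, 118 and 97 shared, and 892 that differed; all 994 and 564 genes called without it kept their call. Without both number 4 arrays the values were 2327 and 1786 for mature against immature mTECs, of which 981 and 553 were called with them, 485 and 117 for the B cells, 143 and 130 shared, and 976 that differed. The signal range covariate gave 1784 and 1623, 1422 and 1744 for mature mTECs against cTECs, 258 and 333, 373 and 175, 96 and 54 shared, and 1156 that differed.

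Lower genes against cTECs numbered 2629 (mature) and 332 (immature) after median centring, which removes medians over all genes of -0.22 and -0.12, 2777 and 239 without dim genes, and 981 (immature) after quantile normalization. The 11 TEC arrays alone gave 491 and 188 for immature mTECs against cTECs. All probe sets gave 15 in all 3 comparisons and 117 that differed. At least 2-fold in addition, the lower genes were 300, 1852 and 267 in the TEC comparisons; by construction a stricter threshold calls fewer. At adjusted p 0.01 the counts were 522 and 205, 1879 and 1352, 145 and 26, 52 and 4, with 6 and 6 shared and 35 that differed. Of the 29 lists, camera at the preset correlation passed 18, 17, 12 and 15 in the 4 comparisons. With an estimated correlation 1, 0, 0 and 6 passed, and with fry 12, 20, 6 and 7. After quantile normalization 7 passed in immature mTECs against cTECs. Aire in the B cells was 2.63 after quantile normalization (adjusted p = 0.207).

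Leaving out 1 replicate at a time gave 677 to 2397 higher and 290 to 2095 lower for mature against immature mTECs, and 2376 to 3454 and 2443 to 4435 for mature mTECs against cTECs. It gave 154 to 2193 and 53 to 2098 for immature mTECs against cTECs, 38 to 69 and 2 to 8 for the B cells, 8 to 90 shared, 7 to 78 in all 3 comparisons and 35 to 517 that differed. Aire in the B cells lay between 3.00 and 3.37. Reversed with the signal range covariate were Edem1 (-0.10) and Batf3 (0.069) in mature mTECs against cTECs, and there the keratinized (-0.96), immature (-0.84) and interferon (-0.49) lists. In immature mTECs against cTECs, MHC class II (-0.14), keratinized (-0.44), immature (0.011), interferon (-0.13), B-cell activation (-0.43) and immediate-early (-1.49) reversed with it, and in the B cells immediate-early (0.21). MHC class I in immature mTECs against cTECs reversed after quantile normalization (-0.087).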

Other observations

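Genes named after the B lineage were also measured in the epithelium. Of 21 pan-B-cell genes, 7 were higher in mature mTECs than in cTECs (7 adjusted over the list alone), with Blnk, an adaptor of B-cell receptor signalling, at 3.77 and Cd24a at 3.14, and the list did not pass camera (adjusted p = 0.105). Mature splenic B-cell genes were higher for 8 of 18 and lower for 2 (9 and 2 over the list alone), with the low-affinity IgE receptor gene Fcer2a (3.34) and the chemokine receptor gene Ccr7 (2.08) higher and Klf2 (-1.48) lower, adjusted p = 0.0286 and adjusted p = 0.376 with an estimated correlation. Plasma-cell genes were higher for 3 of 14 (3 over the list alone), led by Sec11c (2.36), a signal peptidase gene expressed in secretory cells, and did not pass as a list (adjusted p = 0.0678).

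Among Notch ligands and thymus factors, mature mTECs against immature mTECs had 4 of 15 higher, Foxn1 (1.84) among them, and 1 lower, the Notch ligand gene Jag2 (-1.77), with 4 each over the list alone (list adjusted p = 0.758). Aire partner proteins were higher in immature mTECs than in cTECs for 4 of 20 (9 over the list alone), led by the acetyltransferase gene Ep300 (1.67), adjusted p = 6.57e-06 and adjusted p = 0.473 with an estimated correlation.

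The tests of explanations below were chosen after the results were seen, while the counts of splits were chosen before. For mature against immature mTECs, 2 of the 35 splits of the 8 arrays gave as many genes as the labels, so chance is not excluded by this count: the labels gave 1558 and the highest other split 4664. That other split orders the arrays exactly by signal range and calls several times the labelled count, which points to a structure of the samples. Of the 8 splits that part the arrays of all 4 shared numbers, the highest other than the labels gave 0. With the signal range as a covariate the labels gave 3407 and the highest other of the 35 gave 687. After quantile normalization the same range-ordered split still gave as many, 1715 against 1713 for the labels. For mature mTECs against cTECs 1 of 35, the labelled split, gave 8019 and the highest other 2068. The labelled split is itself ordered by signal range, so this count cannot tell cell type from range. With the covariate the labelled split gave 3166 and the highest other, mature mTEC 4 with the cTECs, 2684. After quantile normalization the values were 6924 and 533. For immature mTECs against cTECs 2 of 35 gave as many, 1514 for the labels and 4239 for immature mTEC 3 with the cTECs, again ordered by signal range, so chance is not excluded. The labelled split is ordered by signal range too; after quantile normalization the values were 2007 and 2760, and with the covariate 591 and 201.

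In thymic against splenic B cells, 4 of 19 thymocyte and 1 of 20 dendritic and macrophage markers were higher, and no fibroblast, endothelial or epithelial identity marker was, among 14, 13 and 20. Macrophage RNA is argued against as the source of most rises. The 251 genes at least 4-fold above splenic B cells in thymic B array 1, chosen without array 2, exceeded array 2 by a median of 0.34 (upper quartile 0.76), where C1qa, C1qb, C1qc, Lyz2, Csf1r and Adgre1 did so by 1.52 to 3.38. A share of the rises stays open to it, these transcripts among them. Thymocyte RNA stays open, although the CD19 gate would remove thymocytes. The 19 thymocyte markers lay above the splenic array by medians of 1.04 and 1.16 in the 2 arrays. This restates the rise and cannot tell thymocyte RNA from expression by the B cells. Dendritic cell RNA stays open, since 1 of 8 dendritic-lineage markers, Flt3, passed and their median was 0.69, although the CD19 gate would remove dendritic cells too. Expression by the thymic B cells themselves was not tested.

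Endothelial markers were higher in cTECs than in both mTEC groups. The compressed signal range of the cTEC arrays is argued against as the whole cause, since after quantile normalization the list's medians were -1.65 and -1.37, against -1.55 for mature mTECs as deposited. Endothelial RNA in the cTEC sort stays open, although the EpCAM gate would remove endothelial cells. That 8 of 13 markers were lower in both mTEC groups is the pattern itself. It cannot tell such RNA from expression by cTECs. Cdh5 reached 7.03, 7.94 and 7.95 on the cTEC arrays and Pecam1 6.85, 8.34 and 7.98. Expression of these genes by cTECs was not tested.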
